A study of Homo sapiens with 42 samples.

How the data were processed

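The series holds 42 RNA sequencing libraries from 2 human airway epithelial cell lines, NuLi-1 and CuFi-1. Both were exposed to 1 of 2 strains of the bacterium Pseudomonas aeruginosa, coded strain-3873 and strain-801829 here after the library titles, for 2, 5 or 8 h, and each line has a control group. The libraries form 14 groups of 3. The labels give no collection time or mock treatment for the controls, and they do not say whether replicates are separate cultures. The library Cufi_2h_3872_R1, whose title carries another strain code, was used as replicate 1 of the CuFi-1 2 h group of strain-3873. The control titles carry a strain code as well, while their source fields read control.

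The deposited values are integer read counts per gene, made with featureCounts 2.0.0 over exons grouped by gene, per the file headers, which name the RefSeq annotation of GRCh38.p13 and show no option for strand, read pairs or reads with several matches. Reads were demultiplexed with bcl2fastq 2.20.0, checked with FastQC, trimmed with Trimmomatic and aligned with STAR 2.6.1b, and the submitters tested expression with DESeq2, per the submitters' processing notes. The series matrix and the files per sample held the same counts, with 0 differing values, so taking the counts from the other source gave nothing to compare. The labels describe sequencing of host and bacterial RNA together, but the tables held no bacterial genes, so the planned account of bacterial genes gave no value.

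The tables had 44666 gene rows, of which 36132 (80.9%) matched a RefSeq symbol. XIST, TSIX and Y-linked genes (207) were left out. Of the rest, 5048 are copies on alternate or unplaced sequences, and 2675 genes have at least 1 such copy. Reads of a gene and its copies could be split by the counting, so the values of such genes are uncertain. TNF, with 7 copies, had 0 to 1 counts per library, LDHA 0 to 841 and HSF1 0 to 585. The counting used no strand option, so overlapping and antisense genes cannot be told apart either.

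Library totals ranged from 42003845 to 76118539 counts, and 28507 to 30399 genes had a count. A level of 3 counts, the most that a count of 0 allows, corresponds to 0.0394 to 0.0714 CPM (counts scaled to a library total of 1e+06). Such limits cover counting error only, since the reads carry no molecular identifiers.

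Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and data.table (1.17.8). Genes were kept with the function filterByExpr over the 14 groups, which left 25427, of which 1871 have copies or are copies. TMM scaling factors ranged from 0.884 to 1.09. A robust quasi-likelihood model with 1 mean per group was fitted to the 42 libraries, with 28 residual degrees of freedom and a biological coefficient of variation of 0.157. Log2 fold changes, their standard errors (SE) and two-sided p-values came from edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment in each comparison, and a gene was called at an adjusted p under 0.05. Intervals are 95% intervals from the SE. Levels are CPM with TMM factors, as means ± SD.

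There were 20 comparisons. Infection compares the 6 infected libraries of a line and time with its 3 controls, the strains weighted equally. The strain comparison is strain-801829 minus strain-3873. The time comparison sets 5 h or 8 h against 2 h in infected cells. The control comparison is CuFi-1 minus NuLi-1. The infection by line comparison is the infection effect in CuFi-1 minus that in NuLi-1.

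The gene lists, the rule for named genes, the model, the comparisons and the alternative settings below were chosen before the data were examined, except where stated. Of 31 lists, 30 had tested members, and the mitochondrially encoded list had 0 members in the tables. Each list was tested with limma's camera at a preset correlation of 0.01, with adjustment over the 30 lists of a comparison, and again with the correlation estimated from the data and with fry. List p-values are adjusted throughout. Counts of called members are given over all genes and adjusted over the list alone, the latter only where they differ. Of 600 list tests, 186 passed with the preset correlation and 15 with the estimated one.

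The rule for named genes takes the 6 called protein-coding genes with the largest rise and the 6 with the largest fall, at a mean of at least 5 CPM and with no overlap between the libraries of both sides, up to 3 rising and 3 falling called members of each list at a mean of at least 1 CPM, and a panel of 12 genes, CFTR, CXCL8, IL6, CXCL1, CCL20, IL1B, TNF, NFKBIA, TNFAIP3, ICAM1, HMOX1 and MUC5AC. In the infection by line comparison no condition on overlap applies. Of the panel, 11 genes were tested and TNF was not. The genes in the text were picked by hand from that set after their values were seen, passing over genes with copies and near-identical families. The named set was shortened once after the left-out-library values were seen, and the shorter set was not kept. The panel genes other than TNF and MUC5AC were carried through every infection, time, control and by-line comparison. Named outside this choice, after their values were seen, were FOXJ1, SCGB1A1 and, for counts of 5 or fewer, LINC00696, NBPF25P, KLF13_2 and BRD2.

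The steps were tested on simulated counts with 200 changed genes. For the NuLi-1 2 h infection comparison, run on 24871 genes, 73.1% of changes of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold were recovered, with 8 false calls. For the CuFi-1 2 h strain comparison, run on 24859 genes, the shares were 71.6%, 88.1% and 100%, with 13 false calls.

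The file names carry 3 sequencing run codes. Run 1 held all 2 h and 5 h libraries and NuLi-1 control replicate 3. Run 2 held the 8 h libraries except Nuli_8h_801829_R2 and Nuli_8h_801829_R3, which were in run 3 with the other controls of both lines. No CuFi-1 control shared a run with an infected CuFi-1 library.

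The alternative settings were RLE factors, total counts with no factors, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, the run as a term, thinning to the smallest library and leaving out each library in turn. For NuLi-1 at 8 h the infection effect was also fitted within run 3, on 2 controls and the 2 libraries of strain-801829 there. A fit without genes that have copies was added after seeing the data. Settings that drop libraries or counts also changed which genes passed the filter, with 22261 tested within run 3. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.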

Results

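The data are counts of human gene transcripts in bronchial epithelial cells infected with Pseudomonas aeruginosa, a bacterium that colonises airways in cystic fibrosis. NuLi-1 was derived from normal bronchial epithelium and CuFi-1 from cystic fibrosis bronchial epithelium, each from 1 donor, so line and donor cannot be separated. Each line has 3 control libraries, and 3 infected libraries for each of 2 strains at 2, 5 and 8 h, 42 in all. The library titles carry the strain codes, and infected libraries are named here by their titles. Nuli_2h_3873_R2, for example, is replicate 2 of NuLi-1 at 2 h with strain-3873. Totals ranged from 42003845 to 76118539 counts per library. Over the 3790 genes used in a principal component analysis, the first component held 73.7% of the variance and separated the lines. On it, Cufi_2h_801829_R2 stood at 46.4, apart from the other 5 CuFi-1 2 h libraries at 59.9 to 71.7.

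At 2 h after infection, NuLi-1 cells had much lower levels of hypoxia and glycolysis genes than controls. ENO2, a glycolytic enzyme (chromosome 12, 6914580 to 6923697, GRCh38.p13), stood at 29.1 ± 1.33 CPM (SD, n = 6) against 182 ± 8.52 (n = 3), a log2 fold change of -2.65 ± 0.077 (SE) with an adjusted p of 2.13e-24. PFKFB4 changed by -2.02 ± 0.11 and ANGPTL4 by -1.93 ± 0.12. Outside the list, the creatine transporter SLC6A8 changed by -2.21 ± 0.066. Of the 25 members tested, 24 fell and 0 rose, also when adjusted over the list alone, with a median of -1.14 (camera adjusted p = 6.9e-35, and p = 0.000402 with estimated correlation). Against the 1 control in the same run the median was -1.27.

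Inflammatory signals rose in part at this time. The cytokine LIF went from 3.02 ± 0.265 to 11 ± 2.37 CPM (1.86 ± 0.19), and the chemokines CCL2 (1.73 ± 0.32), CXCL2 (1.1 ± 0.2), CXCL1 (1.09 ± 0.23), CCL20 (1.06 ± 0.26) and CXCL8 (0.8 ± 0.21) were higher. Among 32 cytokines and chemokines, 13 rose and 3 fell (13 and 4 over the list alone, camera adjusted p = 0.0801). Of 21 NF-kB targets, 4 rose and 3 fell, with a median of -0.02 that became 0.11 with total counts (camera adjusted p = 0.949). NFKBIA (-0.03 ± 0.13, adjusted p = 0.869), TNFAIP3 (0.36 ± 0.18, 0.125), ICAM1 (-0.43 ± 0.18, 0.0592), IL6 (0.52 ± 0.24, 0.0792) and IL1B (0.43 ± 0.24, 0.159) were not called. IL6 was called without NuLi-1 control replicate 3 (0.73, adjusted p = 0.0406) and with total counts (0.65, 0.0254), and TNFAIP3 with total counts (0.48, 0.0295). With only the groups compared TNFAIP3 (0.35, 0.000496), ICAM1 (-0.44, 0.00163), IL6 (0.51, 0.039) and IL1B (0.42, 0.00187) were all called. TNIP3 rose by 1.62 ± 0.28. Among 33 interferon-stimulated genes, 22 rose and 2 fell (22 and 3 over the list alone), with a median of 0.43 (camera adjusted p = 3.01e-05, but adjusted p = 0.666 with estimated correlation). Examples are DDX58 (0.99 ± 0.1), XAF1 (0.87 ± 0.11) and IFIT1 (0.83 ± 0.14).

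Other groups moved as well in NuLi-1 at 2 h. Of 35 ribosomal protein genes, 26 fell and 0 rose (28 and 0 over the list alone, 18 and 1 with total counts), with a median of -0.28 (camera adjusted p = 4.94e-08, and p = 0.302 with estimated correlation). RPL18 changed by -0.42 ± 0.051. Of 11 metallothionein and zinc genes, 5 fell and 1 rose (7 and 1 over the list alone), with a median of -0.74 (camera adjusted p = 0.0179, and p = 0.302 with estimated correlation), with MT1X at -0.85 ± 0.056. ITGA5 (-1.6 ± 0.084), SERPINE1 (-1.28 ± 0.11), AXL (-0.82 ± 0.071), DDIT3 (-1.14 ± 0.092) and HMOX1 (-0.82 ± 0.19) fell. PPARGC1B (1.71 ± 0.084), cyclin D1 (CCND1, 0.96 ± 0.071), TFRC (0.88 ± 0.073) and CFTR, the chloride channel altered in cystic fibrosis (8.29 ± 1.15 against 4.1 ± 1.05 CPM, 1.01 ± 0.2), rose. Of 31 cell cycle genes, 16 rose and 2 fell (17 and 2 over the list alone, median 0.14, camera adjusted p = 0.00186, and p = 0.302 with estimated correlation).

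In NuLi-1 at 2 h, 10295 of 25427 genes were called, 5264 higher and 5031 lower, of which 721 and 670 changed at least 2-fold. With total counts in place of TMM factors the split was 7380 higher and 3216 lower, as the median of all genes moved from 0.01 to 0.14. With the sequencing run as a term 6502 genes were called, 3182 higher and 3320 lower. CCL20 (0.96), CXCL8 (0.64) and CFTR (0.71) were then no longer called. Under this term 9 interferon-stimulated genes were higher and 4 lower (median 0.3), 4 cytokines and chemokines higher and 2 lower, and 0 NF-kB targets higher and 3 lower. In the uninfected cells, the control of run 1 stood above the other controls by a median of 0.25 over the interferon-stimulated genes.

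At 5 h, NuLi-1 cells had a broad rise of NF-kB targets and chemokines. IL17C went from 0.489 ± 0.0753 (n = 3) to 7.6 ± 1.5 CPM (n = 6), a log2 fold change of 3.96 ± 0.47, with an adjusted p of 1.32e-07. CCL20 (chromosome 2, 227813842 to 227817556), rose by 2.71 ± 0.27 to 74.9 ± 14.3 CPM, and CXCL8 (chromosome 4, 73740569 to 73743716), by 1.95 ± 0.22. CXCL2 (1.83 ± 0.21), CXCL1 (1.73 ± 0.24) and CXCL3 (1.56 ± 0.22) rose too. Of the 21 NF-kB targets, 16 rose and 0 fell (17 over the list alone), with a median of 0.69 (camera adjusted p = 1.9e-09, and p = 0.27 with estimated correlation). They include TNFAIP3 (1.4 ± 0.19), BIRC3 (1.22 ± 0.14), ICAM1 (0.86 ± 0.19) and NFKBIA (0.81 ± 0.13). Of 32 cytokines and chemokines, 17 rose and 0 fell, with a median of 0.67 (camera adjusted p = 6.96e-07, and p = 0.181 with estimated correlation).

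Other genes changed in NuLi-1 at 5 h as well. IL1B (0.85 ± 0.24), TNIP3 (1.61 ± 0.28), CFTR (0.78 ± 0.2), TFRC (0.72 ± 0.073), SLC7A11 (1.06 ± 0.17), CENPE (0.78 ± 0.11) and DDX58 (0.72 ± 0.099) rose. IL6 rose by 0.73 ± 0.24 (adjusted p = 0.0153), a call that was lost without NuLi-1 control replicate 2 (0.55, adjusted p = 0.14). Hypoxia and glycolysis genes remained mostly lower, with 20 that fell and 1 that rose (21 and 1 over the list alone), a median of -0.41 and an adjusted p of 1.17e-12 by camera (adjusted p = 0.114 with estimated correlation). ENO2 stood at -1.17 ± 0.077 and CA9 at -0.86 ± 0.12, and against the 1 control in the same run the median was -0.47. Of 20 actin, SRF and YAP targets, 15 fell and 1 rose (18 and 1 over the list alone), with a median of -0.42 (camera adjusted p = 7.3e-07, and p = 0.181 with estimated correlation). CCN1 (-0.8 ± 0.1) and CCN2 (-0.69 ± 0.18) are in it. CCN4 (-2.12 ± 0.12), GATA3 (-1.13 ± 0.11) and HMOX1 (-0.78 ± 0.19) fell. Interferon-stimulated genes rose in 19 of 33 and fell in 0 (19 and 1 over the list alone, median 0.35, camera adjusted p = 5.65e-05, and p = 0.682 with estimated correlation).

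In NuLi-1 at 5 h, 8757 genes were called, 4378 higher and 4379 lower, of which 346 and 440 changed at least 2-fold, or 5152 higher and 3574 lower with total counts. With the run as a term 4545 were called, 2180 higher and 2365 lower, and the NF-kB targets called higher numbered 8, as did the cytokines and chemokines. Of the interferon-stimulated genes 3 were then higher and 1 lower, with a median of 0.18. ICAM1 (0.72), CFTR (0.48), IL6 (0.4) and IL1B (0.93) were then no longer called.

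At 8 h, NF-kB targets and chemokines were higher in infected NuLi-1 too. CCL20 reached 148 ± 27.4 CPM (n = 6) against 11.3 ± 2.06 in controls (n = 3), a log2 fold change of 3.71 ± 0.29 with an adjusted p of 4.73e-11, and CXCL8 reached 407 ± 73.2 against 62.7 ± 10.2 (2.7 ± 0.23). Of the 21 NF-kB targets, 19 rose and 0 fell, with a median of 1.01 (camera adjusted p = 3.6e-10, and p = 0.6 with estimated correlation). Examples are BCL2A1 (1.85 ± 0.23), BIRC3 (1.75 ± 0.15), TNFAIP3 (1.45 ± 0.19), NFKBIA (1.02 ± 0.13) and ICAM1 (1.18 ± 0.19). Cytokines and chemokines rose in 21 of 32 and fell in 0 (22 and 0 over the list alone), with a median of 0.62 (camera adjusted p = 6.48e-06, and p = 0.6 with estimated correlation). CXCL1 (2.07 ± 0.25) and CXCL2 (1.84 ± 0.21) are among them, and IL7 (1.94 ± 0.16), outside the list, rose too. Epidermal growth factor ligands and pattern recognition genes also held members that rose, such as EREG (1.69 ± 0.2), HBEGF (0.86 ± 0.15), TLR2 (0.95 ± 0.12), IRAK2 (0.93 ± 0.11) and IRAK3 (1.11 ± 0.082), although neither list passed camera. In the former 7 of 24 rose and 3 fell (adjusted p = 0.21), and in the latter 13 of 24 rose and 6 fell (14 and 6 over the list alone, adjusted p = 0.0952).

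Elsewhere in NuLi-1 at 8 h, TNIP3 (2.07 ± 0.28), CYP1B1 (1.15 ± 0.1), GCLM (0.99 ± 0.095), and FAS (1.01 ± 0.092) rose. CCN4 (-1.79 ± 0.11), EPHB3 (-1.08 ± 0.091), SRF (-0.73 ± 0.06) and the mucin MUC5B (-0.89 ± 0.17) fell. Among actin, SRF and YAP targets 13 fell and 0 rose (median -0.47, camera adjusted p = 0.000558, and p = 0.6 with estimated correlation), including ACTA2 (-0.78 ± 0.22), whose call was lost without NuLi-1 control replicate 1 (-0.59, adjusted p = 0.0545). Interferon-stimulated genes went both ways, with 9 that rose, such as IFI44 (0.52 ± 0.098), and 11 that fell, such as OASL (-0.6 ± 0.13), or 10 and 11 over the list alone (camera adjusted p = 0.854). Hypoxia and glycolysis genes did as well, with 6 that rose and 11 that fell (7 and 11 over the list alone, camera adjusted p = 0.705). CFTR rose by 0.53 ± 0.2 (adjusted p = 0.0265), a call lost without NuLi-1 control replicate 1 (0.34, adjusted p = 0.22), control replicate 2 (0.55, 0.0568), Nuli_8h_3873_R2 (0.49, 0.052) or Nuli_8h_801829_R1 (0.47, 0.0579). IL1B (0.69 ± 0.24, adjusted p = 0.0183) lost its call without control replicate 2 (0.61, 0.0884), control replicate 3 (0.65, 0.0685) or Nuli_8h_3873_R1 (0.56, 0.0561). HMOX1 (-0.52 ± 0.19, adjusted p = 0.0257) lost its call without control replicate 3 (-0.34, 0.217), Nuli_8h_3873_R2 (-0.44, 0.0677) or Nuli_8h_801829_R3 (-0.48, 0.0543), and with no filter (-0.48, 0.0597). IL6 was not called (0.33 ± 0.24, adjusted p = 0.266), but was within 1 run (0.79, 0.0285).

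In NuLi-1 at 8 h, 12073 genes were called, 5495 higher and 6578 lower, of which 567 and 787 changed at least 2-fold. With the run as a term 8046 were called (3982 higher and 4064 lower), with ACTA2 (-0.94), CFTR (0.51), HMOX1 (-0.42) and IL1B (0.49) no longer among them, and with 17 NF-kB targets and 15 cytokines and chemokines called higher. The 1 run that held controls and infected libraries of this time had 2 NuLi-1 controls and 2 infected libraries, both of strain-801829, so a fit within it does not cover strain-3873. There 7228 were called (3928 higher and 3300 lower), and 18 of the 21 NF-kB targets and 20 cytokines and chemokines rose and 0 fell. Of the interferon-stimulated genes 10 rose and 4 fell (median 0.02, against -0.1 over all libraries), and of the hypoxia and glycolysis genes 5 rose and 6 fell. CXCL1 (2.29, adjusted p = 0.0694), ICAM1 (1.42, 0.0706) and CFTR (0.5, 0.0927) were not called.

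In CuFi-1 at 2 h, hypoxia and glycolysis genes were also lower, while cytokines were higher. ENO2 stood at 33.6 ± 6 CPM (n = 6) against 150 ± 13.2 in controls (n = 3), a log2 fold change of -2.17 ± 0.077 with an adjusted p of 2.04e-21. CA9 changed by -2.11 ± 0.13 and ALDOC by -1.47 ± 0.056. Of the 25 tested members, 24 fell and 0 rose, with a median of -0.96 (camera adjusted p = 1.5e-43, and p = 7.47e-05 with estimated correlation). LIF (2.14 ± 0.21), CXCL2 (2.02 ± 0.22), CXCL1 (1.9 ± 0.26), CXCL8 (1.15 ± 0.21), CCL20 (1.15 ± 0.27) and IL6 (1.41 ± 0.26, at 1.7 ± 0.218 CPM) rose. Of 32 cytokines and chemokines, 17 rose and 1 fell, with a median of 1.02 (camera adjusted p = 0.000978, and p = 0.454 with estimated correlation). Of 21 NF-kB targets, 12 rose and 0 fell, with a median of 0.34 (camera adjusted p = 3.52e-05, and p = 0.592 with estimated correlation), among them BCL2A1 (2.09 ± 0.25), TNFAIP3 (1.05 ± 0.19) and ICAM1 (0.73 ± 0.19). NFKBIA (0.26 ± 0.13, adjusted p = 0.157) and IL1B (0.38 ± 0.27, 0.343) were not called, but both were with only the groups compared (0.25, adjusted p = 0.00342, and 0.37, 0.0257).

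Several further groups rose in CuFi-1 at 2 h. Of 33 interferon-stimulated genes, 20 rose and 0 fell (21 and 1 over the list alone), with a median of 0.32 (camera adjusted p = 5.06e-06, and p = 0.61 with estimated correlation), such as IFIT3 (0.65 ± 0.11) and OAS2 (0.57 ± 0.11). Of 25 cholesterol synthesis genes, 12 rose and 2 fell (median 0.25, camera adjusted p = 0.00133, and p = 0.612 with estimated correlation), with the LDL receptor LDLR at 1.02 ± 0.091. Of 21 p53 targets, 11 rose and 0 fell (median 0.22, camera adjusted p = 0.00012, and p = 0.09 with estimated correlation), with BBC3 at 1.06 ± 0.14. SOCS3 (1.63 ± 0.21), TLR4 (0.92 ± 0.18), IRAK2 (0.91 ± 0.11), EREG (0.93 ± 0.22) and TFRC (0.82 ± 0.073) rose. CYP1A1 (-2.8 ± 0.22), CCN4 (-2.67 ± 0.12) and HMOX1 (-1.79 ± 0.19) fell. CFTR rose by 0.82 ± 0.21 (adjusted p = 0.00264), a call lost without CuFi-1 control replicate 2 (0.59, adjusted p = 0.0559).

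In CuFi-1 at 2 h, 6460 genes were called, 3380 higher and 3080 lower, of which 233 and 386 changed at least 2-fold. The run term left 1219 calls, 606 higher and 613 lower, with the median SE at 0.299 against 0.151. Of the 25 genes named for this comparison and called, 14 kept their call, while CXCL8, CCL20, IL6, TNFAIP3, ICAM1, IFIT3, OAS2, BBC3, SOCS3, EREG and CFTR lost it. The hypoxia and glycolysis genes called lower numbered 23. The NF-kB targets called higher fell from 12 to 1, the cytokines and chemokines from 17 to 3 and the interferon-stimulated genes from 20 to 0, the last with a median of 0.06.

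At 5 h, CuFi-1 showed a concentrated inflammatory rise. CXCL1 went from 7.29 ± 0.754 (n = 3) to 34.4 ± 6.6 CPM (n = 6), a log2 fold change of 2.24 ± 0.26 with an adjusted p of 2.14e-06, and IL36G rose by 2.22 ± 0.26. CCL20 (2.13 ± 0.28), CXCL2 (2.13 ± 0.22), IL1A (1.93 ± 0.29), CXCL3 (1.9 ± 0.24) and CXCL8 (1.8 ± 0.22) rose as well. Of 21 NF-kB targets, 20 rose and 0 fell, with a median of 0.65 (camera adjusted p = 4.23e-23, and p = 0.0337 with estimated correlation), including BCL2A1 (2.13 ± 0.25), ICAM1 (1.6 ± 0.2), TNFAIP3 (1.56 ± 0.19) and NFKBIA (0.59 ± 0.13). Of 32 cytokines and chemokines, 18 rose and 0 fell (24 over the list alone), with a median of 0.96 (camera adjusted p = 6.26e-12, and p = 0.0337 with estimated correlation). Of 24 pattern recognition and signalling genes, 9 rose and 0 fell, with a median of 0.15 (camera adjusted p = 3.57e-06, and p = 0.0337 with estimated correlation), such as IRAK2 (1.35 ± 0.11) and TLR2 (0.93 ± 0.12).

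Growth factor and wound genes followed in CuFi-1 at 5 h, with 7 of 24 that rose and 0 that fell (median 0.3, camera adjusted p = 2.34e-05, and p = 0.318 with estimated correlation). EREG (1.35 ± 0.22), HBEGF (1.09 ± 0.15) and PLAU (0.94 ± 0.14) are in it. DUSP6 (1.59 ± 0.24), SAA2 (0.81 ± 0.12) and ANKRD37 (0.85 ± 0.11) rose, and CCN4 (-1.83 ± 0.11), DKK1 (-0.87 ± 0.18) and CA9 (-0.54 ± 0.13) fell. Hypoxia and glycolysis genes were no longer mostly lower, with 3 that rose, 5 that fell (5 and 6 over the list alone) and a median of -0.01 (camera adjusted p = 0.418). CFTR (0.38 ± 0.2, adjusted p = 0.244), IL6 (0.55 ± 0.26, 0.182) and IL1B (0.69 ± 0.27, 0.0937) were not called, though IL1B was by DESeq2 (0.68, 0.0429). HMOX1 was called at -0.59 ± 0.19 (adjusted p = 0.0406) but not without CuFi-1 control replicate 1 (-0.31, 0.425), control replicate 2 (-0.6, 0.111), Cufi_5h_3873_R2 (-0.56, 0.0789), Cufi_5h_3873_R3 (-0.56, 0.0776), Cufi_5h_801829_R2 (-0.54, 0.0845) or Cufi_5h_801829_R3 (-0.57, 0.0768). It was not called with only the groups compared (-0.59, 0.125) or with no filter (-0.59, 0.0647) either.

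In CuFi-1 at 5 h, 3108 genes were called, 1694 higher and 1414 lower, of which 183 and 115 changed at least 2-fold, and 1501 were called without CuFi-1 control replicate 2 and 1591 without control replicate 1. The run term left 44 calls, 27 higher and 17 lower, with 98.3% of the 3108 keeping their sign. Of the 23 genes named and called, 4 kept their call, namely CXCL2, BCL2A1, IRAK2 and CCN4, and the other 19, among them CXCL1, CCL20, CXCL8, IL36G, TNFAIP3 and ICAM1, lost it. Then 1 NF-kB target, 1 cytokine or chemokine and 0 interferon-stimulated genes were called higher.

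At 8 h, the CuFi-1 response was largest in CCL20 among the chemokines, at 89.8 ± 31.9 CPM (n = 6) against 5.88 ± 0.985 in controls (n = 3), a log2 fold change of 3.93 ± 0.3 with an adjusted p of 2.19e-10. IL36G (3.03 ± 0.26), IL1A (2.92 ± 0.3), CXCL2 (2.89 ± 0.23), CXCL1 (2.86 ± 0.27) and CXCL8 (2.65 ± 0.23) rose. All 21 NF-kB targets rose, with a median of 1.12 (camera adjusted p = 1.1e-22, and p = 0.0802 with estimated correlation), among them BCL2A1 (3.13 ± 0.26), TNFAIP3 (2.16 ± 0.2), ICAM1 (2.01 ± 0.2) and NFKBIA (1.12 ± 0.13). Among cytokines and chemokines 24 of 32 rose and 0 fell, with a median of 1.3 (camera adjusted p = 2.7e-10, and p = 0.0802 with estimated correlation), IL1B (1.51 ± 0.27) and IL6 (1.02 ± 0.26) included. Of 24 growth factor and wound genes, 12 rose and 0 fell (13 and 0 over the list alone, median 0.55, camera adjusted p = 1.87e-05, and p = 0.291 with estimated correlation), with EREG at 1.86 ± 0.22, HBEGF at 1.48 ± 0.16 and PLAU at 1.32 ± 0.14.

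HMOX1, which was lower than control in CuFi-1 at 2 h, was higher at 8 h, at 172 ± 28.5 against 82.1 ± 27.9 CPM (1.07 ± 0.2, adjusted p = 0.000126). Of 16 iron handling genes, 9 rose and 0 fell, with a median of 0.25 (camera adjusted p = 0.00208, and p = 0.0802 with estimated correlation). GCLM (0.99 ± 0.093), SAA2 (1.27 ± 0.12), DUSP6 (1.8 ± 0.24), IRAK2 (1.72 ± 0.12), TLR2 (1.21 ± 0.12) and the sterol enzyme SQLE (0.74 ± 0.099) rose, while another sterol enzyme, DHCR24, fell (-0.6 ± 0.07). Of 33 interferon-stimulated genes, 14 fell and 1 rose, with a median of -0.25 (camera adjusted p = 0.00127, and p = 0.807 with estimated correlation), such as IFIT1 (-0.53 ± 0.13) and MX2 (-0.52 ± 0.14). Both lost their call with only the groups compared (-0.53, adjusted p = 0.0516, and -0.52, 0.0598). CCN4 (-1.93 ± 0.11), MUC5B (-0.64 ± 0.18) and the water channel AQP3 (-0.6 ± 0.12) fell. CFTR was not called, at 2.1 ± 0.532 against 2.17 ± 0.728 CPM (-0.06 ± 0.2, adjusted p = 0.871, 95% interval -0.48 to 0.36).

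In CuFi-1 at 8 h, 8794 genes were called, 4375 higher and 4419 lower, of which 386 and 354 changed at least 2-fold, or 3579 higher and 5232 lower with total counts. The run term left 2069 calls (1222 higher and 847 lower), with all 21 NF-kB targets and 14 cytokines and chemokines called higher and 9 interferon-stimulated genes lower. IL1B (1.26), IL6 (1.05), HMOX1 (0.95) and AQP3 (-0.69) were no longer called.

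**Figure D1:**
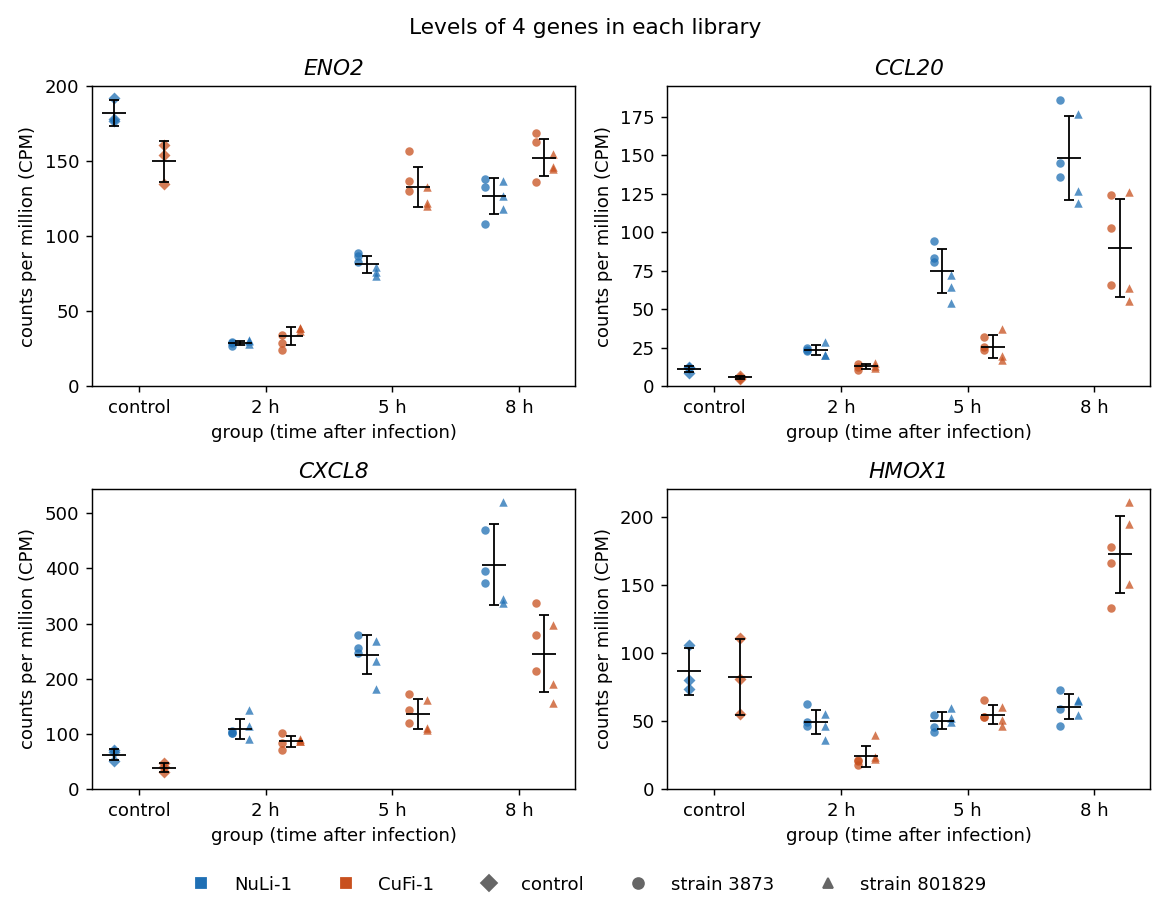
Levels (CPM) of ENO2, CCL20, CXCL8 and HMOX1 in each library, by group on the horizontal axis. Points are libraries, horizontal marks are means and bars are 1 SD over 3 control or 6 infected libraries, and mean CCL20 reached 148 CPM in NuLi-1 and 89.8 CPM in CuFi-1 at 8 h.

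**Figure D2:**
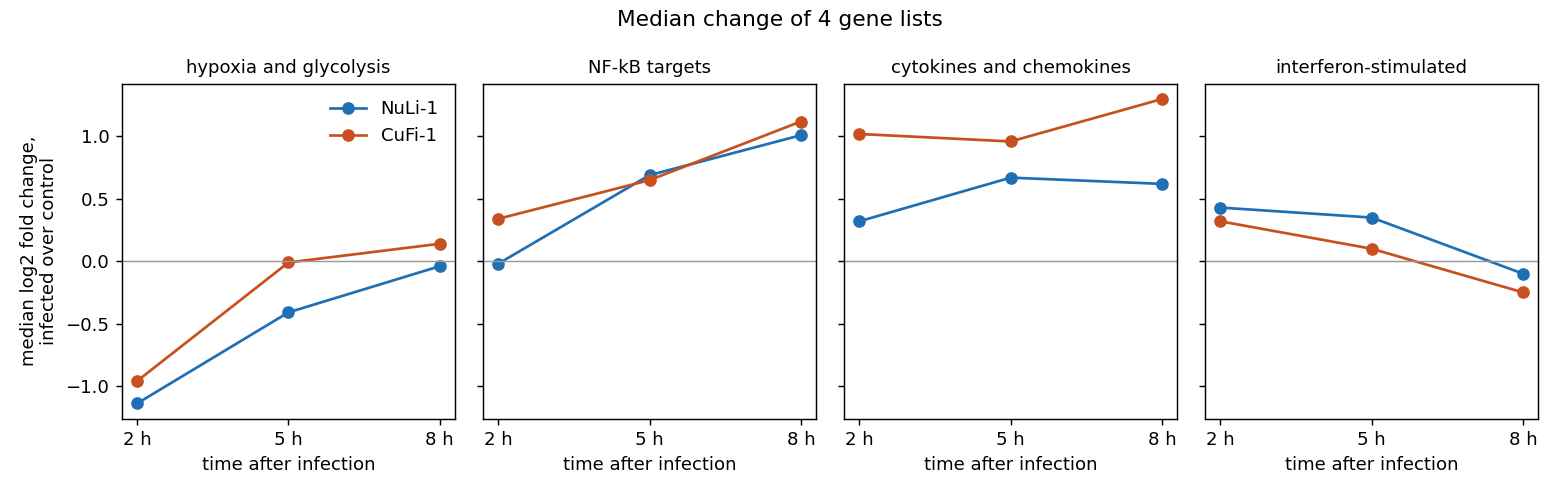
Median log2 fold change of infected over control cells for 4 gene lists at 2, 5 and 8 h, with 1 point per line and time and no error bars. The hypoxia and glycolysis medians lay at -1.14 in NuLi-1 and -0.96 in CuFi-1 at 2 h, and the NF-kB medians at 1.01 and 1.12 at 8 h.

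The time comparison used infected cells alone, so it does not depend on the controls. From 2 to 5 h in NuLi-1, 24 of 25 hypoxia and glycolysis genes rose and 0 fell, with a median of 0.84 (camera adjusted p = 5.43e-52, and p = 1.74e-05 with estimated correlation). ENO2 rose by 1.48 ± 0.067 (adjusted p = 8.36e-18, n = 6 against 6) and ANGPTL4 by 1.64 ± 0.1. Of 35 ribosomal protein genes, 33 rose and 0 fell (median 0.28, adjusted p = 0.00778 with estimated correlation), and of 11 metallothionein and zinc genes 5 rose and 0 fell (median 0.5, adjusted p = 0.0447 with estimated correlation). Of 21 NF-kB targets, 19 rose and 0 fell (21 and 0 over the list alone, median 0.56, camera adjusted p = 1.93e-17, and p = 0.0788 with estimated correlation), and CCL20 (1.66 ± 0.2), ICAM1 (1.29 ± 0.15), CXCL8 (1.15 ± 0.16), TNFAIP3 (1.04 ± 0.15), NFKBIA (0.84 ± 0.1) and CXCL1 (0.64 ± 0.18) rose. MAT2A fell by 0.93 ± 0.046. CFTR (-0.23 ± 0.15, adjusted p = 0.315), IL6 (0.21 ± 0.19, 0.462), IL1B (0.42 ± 0.19, 0.118) and HMOX1 (0.04 ± 0.16, 0.901) were not called, but IL1B was with only the groups compared (0.42, 0.0412). The comparison called 5832 genes, 2955 higher and 2877 lower, or 1723 higher and 5172 lower with total counts, as the median of all genes moved from -0.02 to -0.10.

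From 2 to 8 h in NuLi-1, all 25 hypoxia and glycolysis genes rose, with a median of 1.16 (camera adjusted p = 5.49e-30, and p = 0.00116 with estimated correlation). ENO2 rose by 2.12 ± 0.068, CCL20 by 2.66 ± 0.2, CXCL8 by 1.9 ± 0.17, ICAM1 by 1.61 ± 0.15, TNFAIP3 by 1.09 ± 0.15, NFKBIA by 1.05 ± 0.11, CXCL1 by 0.98 ± 0.18 and IGFBP3 by 1.99 ± 0.12 (n = 6 against 6). Of 21 NF-kB targets, 20 rose and 0 fell (median 0.89, camera adjusted p = 1.03e-12, and p = 0.265 with estimated correlation). Of 33 interferon-stimulated genes, 20 fell and 0 rose (21 and 0 over the list alone, median -0.49, camera adjusted p = 2.8e-06, and p = 0.682 with estimated correlation), with USP18 at -0.9 ± 0.087 and MX2 at -0.89 ± 0.12. MAT2A (-1.36 ± 0.047), CEBPA (-1.5 ± 0.16) and CFTR (-0.48 ± 0.15) fell, and IL6 (-0.19 ± 0.19, adjusted p = 0.425), IL1B (0.26 ± 0.19, 0.266) and HMOX1 (0.31 ± 0.16, 0.113) were not called. The comparison called 12451 genes, 5547 higher and 6904 lower, or 3768 and 9586 with total counts, as the median of all genes moved from -0.08 to -0.21. All 2 h libraries were in another run than the 8 h ones, and with the run as a term 3582 genes were called, 1950 higher and 1632 lower. CFTR (-0.2), MX2 (-0.8) and CXCL1 (1.36) were then not called. Of the interferon-stimulated genes 3 were then lower, with a median of -0.2, while 17 NF-kB targets were higher.

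From 2 to 5 h in CuFi-1, 24 of 25 hypoxia and glycolysis genes rose and 0 fell, with a median of 0.96 (camera adjusted p = 1.42e-41, and p = 0.000107 with estimated correlation). ENO2 rose by 2 ± 0.068 (adjusted p = 4.54e-22, n = 6 against 6), SLC2A3 by 1.77 ± 0.21, CA9 by 1.57 ± 0.11 and PGF by 1.56 ± 0.1. HMOX1 (1.2 ± 0.16), CCL20 (0.98 ± 0.2), ICAM1 (0.87 ± 0.15), CXCL8 (0.65 ± 0.16) and TNFAIP3 (0.51 ± 0.15) rose. AEN (-1.12 ± 0.071), MYC (-1.02 ± 0.069) and IL6 (-0.86 ± 0.2) fell. Of 21 NF-kB targets, 14 rose and 0 fell (15 and 1 over the list alone, median 0.33, camera adjusted p = 0.000198, and p = 0.622 with estimated correlation). NFKBIA rose by 0.33 ± 0.1, a call lost without Cufi_5h_801829_R3 (0.27, adjusted p = 0.0597). CFTR fell by 0.44 ± 0.16 (adjusted p = 0.0345), a call lost without Cufi_2h_3873_R2 (-0.35, 0.128), Cufi_2h_801829_R1 (-0.39, 0.0914), Cufi_5h_3873_R1 (-0.38, 0.101), Cufi_5h_801829_R1 (-0.43, 0.0625) or Cufi_5h_801829_R2 (-0.35, 0.115). CXCL1 (0.34 ± 0.18, 0.183) and IL1B (0.31 ± 0.21, 0.293) were not called. The comparison called 7727 genes, 3763 higher and 3964 lower.

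From 2 to 8 h in CuFi-1, HMOX1 rose by 2.86 ± 0.17, from 24.2 ± 7.89 to 172 ± 28.5 CPM (adjusted p = 2.16e-14, n = 6 against 6), and CYP1A1 by 2.98 ± 0.2. CCL20 (2.77 ± 0.21), ENO2 (2.19 ± 0.068), ERO1A (2.08 ± 0.069), IL36G (1.89 ± 0.18), CXCL8 (1.49 ± 0.16), ICAM1 (1.28 ± 0.15), IL1B (1.13 ± 0.21), TNFAIP3 (1.12 ± 0.15), CXCL1 (0.96 ± 0.19) and NFKBIA (0.86 ± 0.1) rose. Of 25 hypoxia and glycolysis genes, 24 rose and 0 fell (median 1.19, camera adjusted p = 6.09e-30, and p = 0.00118 with estimated correlation), and all 21 NF-kB targets rose (median 0.86, camera adjusted p = 8.79e-11, and p = 0.371 with estimated correlation). Of 33 interferon-stimulated genes, 26 fell and 0 rose (median -0.56, camera adjusted p = 2.5e-10, and p = 0.454 with estimated correlation), with MX2 at -1.02 ± 0.12. AEN (-1.7 ± 0.073), NOL6 (-1.52 ± 0.055) and CFTR (-0.88 ± 0.16) fell, and IL6 was not called (-0.39 ± 0.2, adjusted p = 0.107), but was with only the groups compared (-0.39, 0.0294). The comparison called 11495 genes, 5672 higher and 5823 lower, or 4752 and 6825 with total counts. With the run as a term 2120 were called, 1115 higher and 1005 lower. CFTR (-0.69), MX2 (-1.04), CXCL1 (1.48), IL1B (0.76), NFKBIA (1.02) and TNFAIP3 (1.28) were then not called. The interferon-stimulated genes called lower went from 26 to 4, and the NF-kB targets called higher from 21 to 11.

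The strains were compared within each line and time, 3 libraries against 3, as strain-801829 minus strain-3873. Of 30 gene lists, those that passed camera numbered 3 higher and 3 lower with strain-801829 in NuLi-1 at 2 h, 7 and 3 at 5 h and 2 and 0 at 8 h, and in CuFi-1 10 and 1, 12 and 4, and 2 and 1. With estimated correlation 1 passed in NuLi-1 at 2 h and 0 in the other comparisons. CXCL8, CCL20 and CFTR were not called between strains in any of the 6 comparisons. In NuLi-1 the CXCL8 difference was 0.16 ± 0.23 at 2 h, -0.2 ± 0.23 at 5 h and -0.05 ± 0.23 at 8 h, with a 95% interval of -0.51 to 0.42 at 8 h. In CuFi-1 it was 0.05 ± 0.23, -0.2 ± 0.23 and -0.36 ± 0.23, with an interval of -0.83 to 0.1 at 8 h. CCL20 differed by -0.04 ± 0.28, -0.43 ± 0.27 and -0.14 ± 0.27 in NuLi-1 and by 0.07 ± 0.29, -0.13 ± 0.27 and -0.26 ± 0.27 in CuFi-1. CFTR differed by -0.23 ± 0.22, 0.27 ± 0.22 and -0.3 ± 0.22 in NuLi-1 and by 0.69 ± 0.23 (adjusted p = 0.312), 0.75 ± 0.23 (0.362) and 0.27 ± 0.24 in CuFi-1. Over 11863 genes with at least 5 CPM and no copies, the median absolute log2 difference lay between 0.0543 and 0.0754, and 98.3% to 99.7% of the genes differed by under 0.5, with a median half-width of the 95% interval of 0.172.

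In NuLi-1 at 2 h no gene passed edgeR's test (0 genes, with 1319 at an unadjusted p under 0.05, and 14 by DESeq2). The ciliated and secretory cell list stood higher with strain-801829, with 0 of 13 members called over all genes, 6 over the list alone and a median of 0.6 (camera adjusted p = 5.73e-10, and p = 0.0189 with estimated correlation). SCGB1A1 stood at 10.6 against 2.54 CPM (2.06 ± 0.5, adjusted p = 0.349). FOXJ1 stood at 5.9 against 2 CPM (1.56 ± 0.31, 0.11). Both had the list's lowest p. The count was 2 without Nuli_2h_3873_R1, 1 without Nuli_2h_3873_R2, 4 without Nuli_2h_3873_R3, 6 without Nuli_2h_801829_R1, 9 without Nuli_2h_801829_R2 and 1 without Nuli_2h_801829_R3.

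In NuLi-1 at 5 h 1 gene was called, KLF13_2, a copy on an unplaced sequence (6.87 ± 1.1, adjusted p = 0.0378), with 1218 at an unadjusted p under 0.05 and 9 by DESeq2. The count was 0 without a filter on low counts, with the replicate block, with the run as a term or without genes that have copies, and 4 with only the groups compared. It was 4 without Nuli_5h_3873_R1, 8 without Nuli_5h_3873_R2, 8 without Nuli_5h_3873_R3, 4 without Nuli_5h_801829_R1, 3 without Nuli_5h_801829_R2 and 4 without Nuli_5h_801829_R3. At 8 h 0 genes passed edgeR's test (1557 at an unadjusted p under 0.05, 13 by DESeq2), or 8 with the run as a term. The count at 8 h was 11 without Nuli_8h_3873_R1, 1 without Nuli_8h_3873_R2, 7 without Nuli_8h_3873_R3, 2 without Nuli_8h_801829_R1, 1 without Nuli_8h_801829_R2 and 1 without Nuli_8h_801829_R3.

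In CuFi-1 at 2 h 31 genes differed between strains, 24 higher and 7 lower with strain-801829. PI3 stood at 1600 ± 753 against 487 ± 109 CPM (1.72 ± 0.33, adjusted p = 0.0282, n = 3 each). GJB2 (1.03 ± 0.21), SLC5A1 (0.91 ± 0.18), CA9 (0.78 ± 0.16), ANKRD37 (0.78 ± 0.13), LPAR3 (0.39 ± 0.08) and NDRG1 (0.33 ± 0.072) were higher, and ZNF580 was lower (-0.43 ± 0.093). Hypoxia and glycolysis genes were higher in 3 of 25 and lower in 0, or 13 and 0 over the list alone (median 0.21, camera adjusted p = 3.75e-15, and p = 0.0531 with estimated correlation). All 8 named genes lost their call without Cufi_2h_801829_R2, the library that stood apart in the principal component analysis. There PI3 was at 1.27 (adjusted p = 0.303), GJB2 at 0.67 (0.468), SLC5A1 at 0.76 (0.303), CA9 at 0.45 (0.476), ANKRD37 at 0.72 (0.0931), NDRG1 at 0.25 (0.525), LPAR3 at 0.31 (0.353) and ZNF580 at -0.44 (0.2).

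Other libraries ended some of these calls in CuFi-1 at 2 h. PI3 lost its call without Cufi_2h_3872_R1 (1.68, adjusted p = 0.119), Cufi_2h_3873_R2 (1.91, 0.0606) or Cufi_2h_3873_R3 (1.59, 0.0903). Without the same libraries GJB2 stood at 1.07 (0.097), 1.11 (0.067) and 0.9 (0.116), and SLC5A1 at 0.89 (0.125), 1 (0.0649) and 0.84 (0.0995). CA9 lost its call without Cufi_2h_3873_R2 (0.67, 0.163) or Cufi_2h_3873_R3 (0.71, 0.116). NDRG1 lost it without Cufi_2h_3873_R2 (0.31, 0.15), Cufi_2h_3873_R3 (0.26, 0.172) or Cufi_2h_801829_R3 (0.34, 0.0593), and LPAR3 without the same libraries (0.34, 0.144, then 0.37, 0.0807, then 0.38, 0.0576). ZNF580 lost it without Cufi_2h_3872_R1 (-0.37, 0.245), Cufi_2h_3873_R2 (-0.41, 0.13), Cufi_2h_801829_R1 (-0.45, 0.0743) or Cufi_2h_801829_R3 (-0.41, 0.102). The count was 5 without Cufi_2h_801829_R2, 13 without Cufi_2h_3872_R1, 10 without Cufi_2h_3873_R2, 50 without Cufi_2h_801829_R1 and 66 without Cufi_2h_801829_R3, and without Cufi_2h_3873_R3 it was 28, of which 7 were higher and 21 lower. The number was 17 with no filter, 6 with only the groups compared and 144 by DESeq2. None of the 8 named genes kept its call with only the groups compared (adjusted p of 0.182 to 0.754). With no filter GJB2, SLC5A1, CA9, NDRG1 and ZNF580 lost theirs, and with the run as a term GJB2 (1.03), CA9 (0.77), NDRG1 (0.33) and ZNF580 (-0.43). CA9 and NDRG1 lost theirs with the replicate block (0.77 and 0.33, adjusted p = 0.0558 each), CA9 (0.75, 0.053) and ZNF580 (-0.39, 0.086) after thinning, and NDRG1 with RLE factors (0.33, 0.0566) or without genes that have copies (0.33, 0.0534).

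In CuFi-1 at 5 h 2 genes were called, the noncoding RNA gene LINC00696 (1.15 ± 0.2, adjusted p = 0.0242) and BRD2 (1.85 ± 0.32, adjusted p = 0.0242), which has 6 copies on alternate sequences. LINC00696 lost its call without Cufi_5h_3873_R1 (0.93, 0.23), Cufi_5h_3873_R2 (1.12, 0.0985) or Cufi_5h_801829_R3 (1, 0.17), and 2105 genes had an unadjusted p under 0.05. The count was 0 without Cufi_5h_3873_R2, 3 without Cufi_5h_3873_R1, all lower, and 8 without Cufi_5h_3873_R3, Cufi_5h_801829_R1 or Cufi_5h_801829_R2. It was 0 with only the groups compared, 1 without genes that have copies and 38 by DESeq2. The squamous and cornified envelope list stood higher, with 0 of 19 members called over all genes, 14 over the list alone and a median of 0.51 (camera adjusted p = 1.14e-10, but adjusted p = 0.239 with estimated correlation).

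At 8 h in CuFi-1 the 1 gene called between strains was the pseudogene NBPF25P (-1 ± 0.17, adjusted p = 0.0404), one of a family of near-identical genes. At an unadjusted p under 0.05 there were 2005 genes, and DESeq2 called 38. The call was lost without Cufi_8h_3873_R2 (-0.65, 0.241), Cufi_8h_801829_R2 (-0.98, 0.123) or Cufi_8h_801829_R3 (-1.04, 0.0518). The count was 0 with no filter, with only the groups compared, with the replicate block or after thinning. It was 277 without Cufi_8h_3873_R3, 11 without Cufi_8h_3873_R1, 18 without Cufi_8h_801829_R1 and 2 without Cufi_8h_801829_R3.

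Between uninfected lines, 21 of 30 gene lists passed as lower in CuFi-1 and 0 as higher. TERT, introduced to immortalise both lines, stood at 13.1 ± 4.3 CPM in CuFi-1 against 1980 ± 268 in NuLi-1 (-7.23 ± 0.45, adjusted p = 4.72e-14, n = 3 each). TRPC6 was higher in CuFi-1 (25.7 ± 0.935 against 0.113 ± 0.0857 CPM, 7.71 ± 0.2), as were CYP4F11 (5.8 ± 0.25), PTGS2 (2.06 ± 0.2), KRT15 (1.97 ± 0.15), UGT1A6 (1.92 ± 0.16) and KRT13 (1.47 ± 0.24). Squamous and cornified envelope genes were lower in 13 of 19 and higher in 2, with a median of -2.19 (camera adjusted p = 7.33e-06, and p = 0.244 with estimated correlation), among them SPRR2A (-5.56 ± 0.59). Cell junction genes were lower in 17 of 24 and higher in 1, with a median of -0.68 (camera adjusted p = 1.49e-07, and p = 0.0408 with estimated correlation), with GJB2 at -3.31 ± 0.22 and GJB6 at -3.49 ± 0.36. KRT6B (-4.03 ± 0.36) and KRT14 (-3.86 ± 0.26) were lower as well.

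Host defence lists were among these 21. Of 20 antimicrobial proteins 18 were lower and 1 higher, with a median of -2.11 (camera adjusted p = 1.31e-07, and p = 0.134 with estimated correlation), such as PLA2G2A (-5.14 ± 0.51) and BPIFA1 (-4.01 ± 0.4). SCGB3A1 (-3.76 ± 0.41) was lower too. Cytokines and chemokines were lower in 27 of 32 and higher in 0 (28 and 0 over the list alone), with a median of -1.65 (camera adjusted p = 2.08e-07, and p = 0.136 with estimated correlation), such as CXCL5 (-6.7 ± 0.34), IL36A (-4.93 ± 0.39), IL1B (-2.94 ± 0.3), CXCL1 (-2.6 ± 0.29) and IL6 (-1.61 ± 0.29). NF-kB targets were lower in 13 of 21 and higher in 2 (14 and 2 over the list alone, median -0.54, camera adjusted p = 0.00737, and p = 0.409 with estimated correlation), with ICAM1 at -1.26 ± 0.22, TNFAIP3 at -1.04 ± 0.21 and NFKBIA at -0.54 ± 0.15, the last not called with total counts (-0.29, 0.0714). CCL20 (-0.94 ± 0.3) was lower, and so was CXCL8 (-0.69 ± 0.23, adjusted p = 0.014), a call lost without CuFi-1 control replicate 1 (-0.54, 0.0839) or NuLi-1 control replicate 3 (-0.6, 0.0582), with the run as a term (-0.6) and with total counts (-0.43, 0.112). CD14 (-3.09 ± 0.16), EREG (-3.13 ± 0.25) and MMP3 (-3.89 ± 0.53) were lower.

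Of 19 airway ion transport genes 10 were lower and 2 higher (11 and 2 over the list alone, median -0.47, camera adjusted p = 0.0212, and p = 0.254 with estimated correlation). Of 15 mucin and goblet genes 6 were lower and 0 higher (median -0.65), and the list did not pass (camera adjusted p = 0.106, and p = 0.406 with estimated correlation). CFTR stood at 2.17 ± 0.728 CPM in CuFi-1 and 4.1 ± 1.05 in NuLi-1 (-0.92 ± 0.23, adjusted p = 0.00104). The chloride transporter SLC26A9 (-3.5 ± 0.27), the water channel AQP5 (-3.15 ± 0.35), MUC5B (-2.22 ± 0.21) and SPDEF (-2.47 ± 0.23), were lower. Of 25 cholesterol synthesis genes 24 were lower and 0 higher (median -0.88, camera adjusted p = 5.73e-11, and p = 0.134 with estimated correlation), with LDLR at -1.53 ± 0.1 and PCSK9 at -2.49 ± 0.17. HMOX1 was not called (-0.08 ± 0.22, adjusted p = 0.795). The comparison called 13852 genes, 6724 higher and 7128 lower in CuFi-1, of which 2711 and 2469 differed at least 2-fold, or 10458 higher and 4374 lower with total counts, as the median of all genes moved from 0.02 to 0.27.

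The lines shared many calls. At 2 h 2183 genes were higher and 2053 lower in both lines, against 700 and 609 for independent lists, and at 8 h 3543 and 3636 against 945 and 1143. At 5 h the numbers were 1129 and 933 against 292 and 244. Genes higher in 1 line and lower in the other numbered 93 and 130 at 2 h, 24 and 38 at 5 h and 18 and 26 at 8 h. Across genes called in either line, which are not independent replicates, Pearson's r between the lines was 0.56 at 2 h, 0.465 at 5 h and 0.626 at 8 h. The lines do not share controls. At 2 and 5 h most controls of both lines were in another run than the infected libraries, so a shared effect of run or handling would add to the overlap, and the numbers for independent lists do not allow for it. This holds at 8 h too, as 0 CuFi-1 libraries and 2 of the 6 infected NuLi-1 libraries shared a run with a control of their line.

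The response to infection differed between the lines by a direct test. At 2 h, BCL2A1 had a higher change in CuFi-1, by 1.82 ± 0.33 (adjusted p = 0.000184), as did GDF15 (1.38 ± 0.21), ICAM1 (1.16 ± 0.26), IRAK2 (1.01 ± 0.15) and LDLR (0.86 ± 0.12). SLC7A11 (-1.68 ± 0.24), CYP1A1 (-1.54 ± 0.32) and HMOX1 (-0.97 ± 0.28, adjusted p = 0.0152) had a lower change in CuFi-1, the last a call lost without CuFi-1 control replicate 1 (-0.69, 0.0996) or NuLi-1 control replicate 2 (-0.87, 0.0622), or with only the groups compared (-0.96, 0.0781). Of 35 ribosomal protein genes 22 had a higher change in CuFi-1 and 0 a lower one (26 and 0 over the list alone, 8 and 0 with total counts, median 0.28, camera adjusted p = 1.08e-13, and p = 0.118 with estimated correlation), and of 20 actin, SRF and YAP targets 10 and 0 (13 and 0 over the list alone, 5 and 1 with total counts, median 0.41, camera adjusted p = 2.02e-06, and p = 0.165 with estimated correlation). CFTR (-0.19 ± 0.28, adjusted p = 0.728), CXCL8 (0.35 ± 0.28, 0.463), CCL20 (0.1 ± 0.36, 0.909), IL6 (0.89 ± 0.35, 0.0773), CXCL1 (0.82 ± 0.33, 0.0978), TNFAIP3 (0.69 ± 0.25, 0.0627), NFKBIA (0.29 ± 0.18, 0.319) and IL1B (-0.05 ± 0.36, 0.954) were not called. IL6 was called without NuLi-1 control replicate 2 (1.07, 0.0488), with only the groups compared (0.89, 0.0488) and after thinning (1.05, 0.0364), and CXCL1 (0.82, 0.0216), TNFAIP3 (0.7, 1.82e-05) and NFKBIA (0.29, 0.0134) with only the groups compared. By DESeq2 CXCL1 (0.81, 0.0486) and TNFAIP3 (0.69, 0.0436) were called. There were 4058 calls, 2155 higher and 1903 lower, or 914 higher and 3535 lower with total counts, as the median of all genes moved from 0 to -0.12.

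At 5 h the hypoxia and glycolysis genes had a higher change in CuFi-1 in 12 of 25 and a lower one in 0 (18 and 0 over the list alone), with a median of 0.33 (camera adjusted p = 2.21e-17, and p = 0.0139 with estimated correlation). ENO2 (0.99 ± 0.11, adjusted p = 1.28e-06), PFKFB4 (0.8 ± 0.16) and ITGA5 (0.92 ± 0.12) had a higher change. Cell cycle genes had a lower change in 12 of 31 and a higher one in 0 (16 and 0 over the list alone), with a median of -0.16 (camera adjusted p = 1.98e-09, and p = 0.0139 with estimated correlation). CYP1B1 (-1.08 ± 0.14), SLC7A11 (-1.19 ± 0.24) and CENPE (-0.64 ± 0.16) had a lower change, the last a call lost without NuLi-1 control replicate 2 (-0.51, 0.056). BCL2A1 (1.24 ± 0.33) lost its call without CuFi-1 control replicate 3 (1.18, 0.0547) or NuLi-1 control replicate 2 (1.12, 0.0585), and IL36G (1.18 ± 0.32) without CuFi-1 control replicate 1 (1.14, 0.0561), CuFi-1 control replicate 3 (1.09, 0.0778) or NuLi-1 control replicate 3 (1.03, 0.0632), and with the run as a term (1.03). CFTR (-0.4 ± 0.28, adjusted p = 0.423), CXCL8 (-0.15 ± 0.28, 0.811) and CCL20 (-0.58 ± 0.36, 0.351) were not called, nor were IL6, CXCL1, IL1B, NFKBIA, TNFAIP3 and HMOX1 (adjusted p of 0.385 to 0.845). ICAM1 (0.74 ± 0.26, 0.0726) was called only by DESeq2 (0.74, 0.0429) and with only the groups compared (0.74, 0.0131). There were 2249 calls, 1083 higher and 1166 lower, or 800 and 1656 with total counts. Calls numbered 1123 without NuLi-1 control replicate 2 and 1276 without CuFi-1 control replicate 3.

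At 8 h IL36G (1.75 ± 0.32, adjusted p = 0.00415) and HMOX1 (1.58 ± 0.27, 0.00287) had a higher change in CuFi-1, the latter with a rise in CuFi-1 (1.07) and a fall in NuLi-1 (-0.52). CYP1B1 (-0.91 ± 0.14) and IL23A (-1.04 ± 0.21) had a lower change. With only the groups compared IL23A (-1.03, adjusted p = 0.059), IL36A (1.65, 0.0859), BCL2A1 (1.28, 0.0571) and ICAM1 (0.84, 0.205) were not called. Cytokines and chemokines had a higher change in 7 of 32 and a lower one in 1 (10 and 1 over the list alone, median 0.7, camera adjusted p = 0.00314, and p = 0.651 with estimated correlation). CSF2 (2.16 ± 0.59) lost its call without CuFi-1 control replicate 1 (2.01, 0.0815), CuFi-1 control replicate 3 (1.96, 0.105) or NuLi-1 control replicate 2 (2.12, 0.0852), and IL36A (1.64 ± 0.45) without CuFi-1 control replicate 1 (1.43, 0.0963), CuFi-1 control replicate 3 (1.44, 0.112) or NuLi-1 control replicate 3 (1.3, 0.0794). BCL2A1 (1.28 ± 0.32) lost it without CuFi-1 control replicate 3 (1.22, 0.0689) or NuLi-1 control replicate 2 (1.16, 0.0853). ICAM1 (0.84 ± 0.26, adjusted p = 0.0494) lost it without any 1 of 13 of the 18 libraries. These are the 3 CuFi-1 controls (0.75, 0.9 and 0.86), Cufi_8h_3873_R1 (0.88), Cufi_8h_3873_R2 (0.81), Cufi_8h_3873_R3 (0.81), Cufi_8h_801829_R1 (0.66), NuLi-1 control replicates 2 and 3 (0.84 and 0.76), Nuli_8h_3873_R1 (0.84), Nuli_8h_3873_R3 (0.75), Nuli_8h_801829_R1 (0.75) and Nuli_8h_801829_R2 (0.78), at adjusted p of 0.0501 to 0.134. It was not called with RLE factors (0.79, 0.0617), total counts (0.78, 0.0604), the replicate block (0.83, 0.0582) or no filter (0.78, 0.0979) either, and IL36A not with the run as a term (1.27). CFTR (-0.58 ± 0.28, adjusted p = 0.208), CXCL8 (-0.05 ± 0.28, 0.947) and CCL20 (0.21 ± 0.36, 0.777) were not called, nor was TNFAIP3 (0.72 ± 0.25, 0.0833), which was without Cufi_8h_801829_R2 (0.85, 0.0227), nor IL6, CXCL1, IL1B and NFKBIA (0.138 to 0.799). There were 1757 calls, 957 higher and 800 lower, or 600 and 1421 with total counts, 611 and 1516 with RLE factors, 372 and 1138 with no filter and 903 and 2052 by DESeq2. The count was 1131 with the run as a term and 214 with only the groups compared. It was 261 without NuLi-1 control replicate 2, 411 without CuFi-1 control replicate 3, 879 without CuFi-1 control replicate 1, 1103 without Cufi_8h_3873_R1, 1038 without Cufi_8h_3873_R2 and 2996 without Cufi_8h_3873_R3.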

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

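The counts over other splits of the libraries were chosen after the results were seen, and the tests of the difference between the lines before the data were examined. Each result below was set apart because a direct test found that the change after infection differed between the lines, given as the change in CuFi-1 minus that in NuLi-1. The sequencing run was entered as a term and no other cause of these differences was tested, and 1 donor per line leaves disease, donor and culture history as open explanations.

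At 2 h 4058 genes differed. BCL2A1 (1.82), GDF15 (1.38), ICAM1 (1.16), IRAK2 (1.01) and LDLR (0.86) had a higher change in CuFi-1, and SLC7A11 (-1.68), CYP1A1 (-1.54) and HMOX1 (-0.97) a lower one. HMOX1 lost its call without CuFi-1 control replicate 1 (-0.69, adjusted p = 0.0996) or NuLi-1 control replicate 2 (-0.87, 0.0622), and with only the groups compared (-0.96, 0.0781). In a separate fit of these libraries that pools the strains, the real split called 3698 genes and the highest of the others 8296. Of 100 splits drawn from 7056, 2 called as many. Exchanging infected and control libraries within each line removes the infection effect itself, so these splits do not test a difference between the lines, and whether chance explains it stays open. The split with 8296 kept the 3 NuLi-1 controls in their group and 0 of the CuFi-1 ones, so it kept the effect in NuLi-1 and broke that in CuFi-1. The run term left 3215 calls.

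At 5 h 2249 genes differed, or 1123 without NuLi-1 control replicate 2 and 1276 without CuFi-1 control replicate 3. ENO2 (0.99), PFKFB4 (0.8) and ITGA5 (0.92) had a higher change in CuFi-1, and CYP1B1 (-1.08) and SLC7A11 (-1.19) a lower one. CENPE (-0.64) lost its call without NuLi-1 control replicate 2 (-0.51, adjusted p = 0.056). BCL2A1 (1.24) lost it without CuFi-1 control replicate 3 (1.18, 0.0547) or NuLi-1 control replicate 2 (1.12, 0.0585), and IL36G (1.18) without CuFi-1 control replicate 1 (1.14, 0.0561), CuFi-1 control replicate 3 (1.09, 0.0778) or NuLi-1 control replicate 3 (1.03, 0.0632), and with the run as a term (1.03). In fits that pool the strains 2 of 100 splits called as many genes as the real one (2474), and the highest other called 3839, with the 3 NuLi-1 controls together and 1 CuFi-1 control in its group. As at 2 h, these splits do not test a difference between the lines. The run term left 1925 calls.

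At 8 h 1757 genes differed. The count was 261 without NuLi-1 control replicate 2, 411 without CuFi-1 control replicate 3, 879 without CuFi-1 control replicate 1, 1103 without Cufi_8h_3873_R1, 1038 without Cufi_8h_3873_R2 and 2996 without Cufi_8h_3873_R3. IL36G (1.75) and HMOX1 (1.58) had a higher change in CuFi-1, and IL23A (-1.04) and CYP1B1 (-0.91) a lower one. With only the groups compared IL23A (-1.03, adjusted p = 0.059), IL36A (1.65, 0.0859), BCL2A1 (1.28, 0.0571) and ICAM1 (0.84, 0.205) were not called. CSF2 (2.16) lost its call without CuFi-1 control replicate 1 (2.01, adjusted p = 0.0815), CuFi-1 control replicate 3 (1.96, 0.105) or NuLi-1 control replicate 2 (2.12, 0.0852), and IL36A (1.64) without CuFi-1 control replicate 1 (1.43, 0.0963), CuFi-1 control replicate 3 (1.44, 0.112) or NuLi-1 control replicate 3 (1.3, 0.0794). BCL2A1 (1.28) lost it without CuFi-1 control replicate 3 (1.22, 0.0689) or NuLi-1 control replicate 2 (1.16, 0.0853). ICAM1 (0.84) lost it without any 1 of 13 libraries, at 0.66 without Cufi_8h_801829_R1 to 0.9 without CuFi-1 control replicate 2, with the others in the report, and with RLE factors, total counts, the replicate block or no filter. The run term left 1131 calls, without IL36A (1.27). In fits that pool the strains 1 of 100 splits, the real one, called as many genes (286, highest other 2, against 214 with only the groups compared and the strains apart), but these splits do not test a difference between the lines here either. A count that falls to 261 without 1 control rests on few libraries.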

How the results depend on the processing

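The setting without genes that have copies, the pairing check and the check across runs at 2 h were chosen after seeing the data, and the other settings before. The main limits are the design's. No CuFi-1 control shares a sequencing run with infected CuFi-1 libraries, and controls have no stated collection time. Replicate numbers do not pair the libraries, as the mean correlation of residuals was 0.006 over 273 pairs with the same number and -0.003 over 546 others. Each fit under a setting or with 1 library left out kept at least 2 libraries in an arm, while the check across runs also set 3 libraries against a single control and did not test that difference. Depth limits a count of 0 to at most 0.0714 CPM. In NuLi-1 at 2 h 6863 genes of at least 1 CPM were called between the strain-3873 libraries and control replicates 1 and 2, of another run. Between the strain-801829 libraries and control replicate 3, of the same run, 96.1% of them had the same sign, with a slope of 0.772.

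With the run as a term the infection counts were 6502, 4545 and 8046 in NuLi-1 at 2, 5 and 8 h and 1219, 44 and 2069 in CuFi-1, the 8 h against 2 h counts 3582 in NuLi-1 and 2120 in CuFi-1, and the 8 h by-line count 1131. The term takes up most of the contrast with controls, as the median SE rose from 0.152 to 0.245 in NuLi-1 and from 0.151 to 0.301 in CuFi-1 at 8 h. Of infection calls without it, 97.2% to 99.6% kept their sign. In CuFi-1 this does not test the run, as only NuLi-1 groups span runs. Within 1 run, on 2 controls and 2 libraries of strain-801829, NuLi-1 at 8 h had 7228. In the other settings the cause was not tested. The NuLi-1 5 h strain count of 1 became 0 with no filter, with the replicate block, with the run as a term and without genes that have copies, and the NuLi-1 8 h strain count of 0 became 8 with the run as a term. The CuFi-1 8 h strain count of 1 became 0 with no filter, with the replicate block and after thinning. With no filter the CuFi-1 2 h strain count was 17, and without genes that have copies that at 5 h was 1. DESeq2 gave strain counts of 14, 9 and 13 in NuLi-1 and 144, 38 and 38 in CuFi-1, and 2955 by line at 8 h. With only the groups compared, which leaves fewer libraries, these were 1, 4 and 1, then 6, 0 and 0, and 214. With an estimated correlation 15 list tests passed instead of 186, while fry passed 203.

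With 1 library left out, the infection counts ranged from 8380 to 10217, 6413 to 8497 and 10462 to 11996 in NuLi-1 at 2, 5 and 8 h and from 4869 to 6301 and 6826 to 8967 in CuFi-1 at 2 and 8 h. At 5 h in CuFi-1 they ranged from 1501 (without control replicate 2) to 3080, with 1591 without control replicate 1. Time counts ranged from 5004 to 5458 and 11717 to 12160 in NuLi-1 and from 6962 to 7629 and 10633 to 11435 in CuFi-1, and the control line count from 12589 to 12983. By line they ranged from 2819 to 4755 at 2 h, 1123 (without NuLi-1 control replicate 2, and 1276 without CuFi-1 control replicate 3) to 2650 at 5 h, and 261 (without NuLi-1 control replicate 2) to 2996 (without Cufi_8h_3873_R3) at 8 h, with every other library of that comparison that moved the count named in the report. Strain counts ranged from 1 to 9, 3 to 8 and 1 to 11 in NuLi-1, and from 5 to 66, 0 to 8 and 1 to 277 in CuFi-1, as given by library in the report.

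Of 343 results for single genes, 276 were called, 81 of these lost their call under at least 1 setting, 28 when 1 library was left out, and 0 reversed. The run term ended 61 calls, only the groups compared 18, no filter 9, the replicate block 4, thinning and total counts 3 each, RLE factors 2 and leaving out copies 1. Within 1 run 3 of 30 ended. Calls were gained with only the groups compared (13), DESeq2 (4), 1 library left out (3), total counts (2), thinning (1) and within 1 run (1). Taking counts from the files per sample gave no other values, as both sources are equal.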

Other observations

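The tests of handling or time in culture, of genes with copies and of other splits were chosen after the results were seen. Gene lists that the report leaves out differed most between the uninfected lines. Uninfected CuFi-1 had lower immediate-early and MAPK feedback genes (25 of 33 lower and 3 higher, median -0.81, camera adjusted p = 2.02e-07), nuclear genes of oxidative phosphorylation (22 of 26 lower and 0 higher, or 10 and 1 with total counts, -0.39, 2.15e-07), and integrated stress and unfolded protein response genes (18 of 25 lower and 3 higher, -0.48, 7.83e-05). Also lower were heat shock genes (13 of 19 lower and 1 higher, 14 and 2 adjusted over the list alone, -0.56, 0.00141) and airway basal cell genes (10 of 14 lower and 3 higher, 11 and 3 over the list alone, -0.42, 0.00186). Mesenchymal and fibroblast genes (11 of 17 lower and 1 higher, -0.87, 0.0237) and ciliated and secretory cell genes (7 of 13 lower and 0 higher, -0.96, 0.0483) were lower as well. Immune and endothelial genes (6 of 10 lower and 1 higher, -0.79, 0.0603) and antigen presentation genes (5 of 11 lower and 2 higher, -0.79, 0.0933), of which 7 members have copies, did not pass. With an estimated correlation the adjusted p of these lists was 0.138 to 0.364.

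Below are infection, time and strain results for such lists, none passing with estimated correlation (adjusted p of 0.0888 to 0.807). From 2 to 5 h in NuLi-1, nuclear genes of oxidative phosphorylation rose in 18 of 26 and fell in 0 (20 and 0 over the list alone, 0.17, camera adjusted p = 9.9e-09), or in 6 with total counts (0.09), and from 2 to 8 h in CuFi-1 they fell in 17 and rose in 1 (17 and 2 over the list alone, -0.19, 0.00141). From 2 to 8 h in NuLi-1 they rose in 8 and fell in 6, or 4 and 13 with total counts (0.03 and -0.1), and did not pass. From 2 to 5 h in NuLi-1 aryl hydrocarbon receptor targets rose in 3 of 7 (4 over the list alone, 0.25, or 0.17 with total counts, 0.0102) and NRF2 targets in 4 of 25 (0.05, 0.0318), the latter with a median of -0.04 under total counts. Heat shock genes rose in 9 of 19 and fell in 3 in CuFi-1 at 2 h (0.26, 0.00716). Immediate-early and MAPK feedback genes rose in 13 of 33 and fell in 5 in CuFi-1 at 8 h (13 and 6 over the list alone, 0.29, 0.0271). Inflammasome and cell death genes were higher with strain-801829 in CuFi-1 at 2 h in 0 of 21 (1 over the list alone, 0.11, 0.0137). The mitochondrially encoded list of 13 genes had 0 members in the tables.

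Hypoxia and glycolysis genes were lower at 2 h after infection than in controls in both lines. A run effect as the whole cause is argued against, since 24 of 25 members stayed lower in NuLi-1 and 23 in CuFi-1 with the run as a term, and the median was -1.27 against the control of the same run and -1.16 against the others. Library composition is argued against too, since the median stayed at -0.96 or below with total counts. Handling or time in culture cannot be told apart from infection, since 0 uninfected libraries have a collection time of 2, 5 or 8 h. A response to the bacteria stays open on the same ground.

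NF-kB targets were higher at 8 h after infection than in controls in both lines. In NuLi-1, 18 of 21 members were called higher within 1 run, of strain-801829 alone, which argues against the run as the whole cause. In CuFi-1 21 were with the run as a term, which cannot test it there. Handling or time in culture cannot be told apart from infection here either, for the same reason. A response to the bacteria stays open.

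Genes with copies on alternate sequences varied between replicates. The median log2 SD within groups was 0.418 for 322 such genes and 0.181 for 322 genes without copies matched on level, a ratio of 2.31. Low depth is argued against by the match, with mean levels of 2.2 and 2.16 (log2 CPM). Reads shared with the copies may be the source, and no biological explanation was tested.

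Other splits of the same libraries were counted in fits of the libraries compared that pool the strains, outside the strain comparison, so these real counts differ from those with only the groups compared. For infection only the real one of 84 splits called as many genes. This argues against chance among libraries, not among cultures. In NuLi-1 at 2, 5 and 8 h the real counts were 9584, 8222 and 10327 (highest others 3, 2 and 4), and in CuFi-1 6211, 3869 and 8230 (5, 6 and 2). The same held for time in 100 splits drawn from 462. The counts at 5 and 8 h were 6085 and 11266 in NuLi-1 (1 and 84) and 7860 and 11045 in CuFi-1 (1 and 1). With 3 libraries against 3 the 10 splits are too few. There the real counts are those with only the groups compared, as no strains are pooled. The real count was 12347 between control lines (highest other 0), 1, 4 and 1 between strains in NuLi-1 at 2, 5 and 8 h (4, 4 and 10, with 7, 2 and 5 splits calling as many), and 6, 0 and 0 in CuFi-1 (3, 4 and 3, with 1, 10 and 10 splits).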
